A study of Mus musculus with 10 samples.

How the data were processed

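The data were 10 two-colour Agilent whole mouse genome arrays, up to 4 on a slide, each with RNA of Cdk7 lox/lox fibroblasts after Ad5-CMVCre and after Ad5-CMVGFP infection. Per the labels, primary cells of a mixed 129 x C57Bl/6 background were grown in 10% serum, infected at a multiplicity of 100 and harvested 7 days later, and 1 µg of RNA per sample was labelled. Per the labels, Cy5 held the Cre RNA on 9 arrays and Cy3 on 1 (replicate 4).

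Per the file headers, the deposited scanner tables were made with Agilent Feature Extraction and hold raw median intensity of each spot and of its local background in both channels, and processed intensity that was background subtracted and dye normalized. They also hold the log10 ratio of Cy5 over Cy3, per the file headers. The submitters' processing notes name Feature Extraction 10.1.1 and limma, and the file headers name another version of the former. The authors' deposited value table holds log2 ratios. Its steps are not given in the sources used here, and its direction and scale were found by comparison with the scanner values. Each column correlated across probes with the Cre over GFP ratios computed here at r = 0.967 to 0.999, including replicate 4, where it ran against Cy5 over Cy3 (r = -0.815). The column medians for replicates 1 to 10 were 0.00618, 0.000657, 0.00803, 0.00508, 0.00650, 0.0117, 0.0130, 0.00281, -0.00174 and -0.00633, and how they were centred stays unknown.

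The analysis plan fixed before the data were examined named the mean spot signal, which the scanner tables used here lack. It added that the processed signals would serve if the mean and background columns were missing. Since the background columns were present, the median signal was put in place of the mean and the processed signals were kept as an alternative. This was decided before any test was run, yet the plan can also be read as asking for the processed signals. They gave 7537 changed genes against 7255, and the calls of 4 gene lists differed, as given in the closing section.

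Background was corrected with normexp at an offset of 50, and log2 ratios were normalized by loess within each array, with control spots at weight 0 and outlier spots left out. Loess centres the ratios of probes of similar brightness. Beside 1639 control spots there were 43379 other spots, and the spots of a probe were averaged to 41174 probes. Unversioned accessions were matched to a RefSeq table of the assembly GRCm38.p6, used for names alone since the array was designed on another build, and 23374 probes received 16535 symbols. Other probes were not tested. Probes well above background in the Cre channel on at least 5 arrays or in the GFP channel on at least 5 arrays were kept, and of 4567 genes with several such probes the brightest was used, which left 13881 genes. Of 129 named genes 45 had several probes, and for Acsl1, Ccnh, Cdk2, Cdk6 and Tef another probe had the opposite sign. The rule for named genes took 3 more, which are not reported here.

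Log2 ratios turned to Cre over GFP were tested with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment at 0.05, each array being 1 replicate. Of 35 gene lists 34 had at least 3 members measured (625 of 705 members over all lists), and they were tested with camera at a preset correlation of 0.01. An estimated correlation and fry were alternatives, and with the slide as a block or with trend and robust settings the preset test was run as cameraPR on the statistics of that fit. Named genes were Cdk7, the 12 that rose and the 12 that fell most among those past the threshold with the same sign on all 10 arrays, and up to 2 members that rose and 2 that fell with the smallest p in each list. Where no member of a list passed, the one with the largest ratio was taken, and Ccnh, Mnat1, Cdk1, Cdk2, Cdk4, Cdk6, Cdkn1a and Cdkn2a were always named. No named gene was below background or saturated on all arrays of a condition.

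Median spot signals were 64 to 77 in Cy3 and 168 to 213 in Cy5, over local backgrounds of 16 to 18 and 54 to 58.5, no spot was saturated, and the number of arrays limits the precision. Slides held replicates 1 to 4, 5 to 8, and 9 and 10, and were fitted as a random block and examined within each. Tools were R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8, and Python 3.11.15 with matplotlib 3.10.9. Other settings were no background correction, an offset of 10, processed signals, median centring, Aquantile, the authors' value table, no and a stricter filter on dim probes, the mean of a gene's probes or all probes, a dye term, replicate 4 turned, array weights, trend and robust moderation, and each array left out. Replicate 4 turned means that its ratio was read against its labelled dyes, as if the label were wrong. Leaving out the arrays labelled replicates 1 and 2 together was chosen after seeing the data.

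The fit and the list test were run on simulated log2 ratios of 13881 genes for the Cre and GFP comparison. Background correction, loess, probe choice, dye bias and arrays that stand apart were not simulated. The fit recovered 88.1% of 67 genes changed by 0.5 on the log2 scale. It recovered 92.5% of 67 changed by 1 and 100% of 66 changed by 2, with a false share of 3.07%. Few of the simulated genes were changed, while 52.3% of the real genes passed, so these shares need not hold for the real data. Of 34 simulated lists the 1 that was shifted was called and 0 others were, by camera. The simulated genes varied independently of each other, while the estimated inter-gene correlation of the real lists reached 0.859 for G2 and mitosis genes. The simulation thus does not show how the list test behaves with correlated genes.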

Results

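RNA of primary mouse embryonic fibroblasts homozygous for a conditional (floxed) allele of Cdk7 was profiled on 10 two-colour whole-genome oligonucleotide arrays. Cdk7 encodes the catalytic subunit of the CDK-activating kinase, which it forms with cyclin H (Ccnh) and Mat1 (Mnat1) and which is also part of the general transcription factor TFIIH. Each array compared cells infected with an adenovirus carrying the Cre recombinase, labelled as knockout, with cells infected by an adenovirus carrying GFP, labelled as wild type. RNA was taken 7 days after infection at a multiplicity of 100. The labels describe 10 independent preparations, so the spread between arrays holds both biological and technical variation. The Cre RNA was in Cy5 on 9 arrays and in Cy3 on 1, the array labelled replicate 4. All values are log2 ratios of Cre over GFP, given as mean ± SD over n = 10 arrays unless stated otherwise. Per array, 66.9% to 75.2% of the non-control spots were well above background in the Cre channel and 66.7% to 74.4% in the GFP channel, and the number of arrays limits the precision.

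The first question was whether Cdk7 mRNA was lost in the Cre-infected cells. Its single probe was lower with Cre on all 10 arrays, with a mean of -3.33 ± 1.74 (adjusted p = 0.000390, limma; two-sided exact permutation test over all sign flips, p = 0.00195, the smallest that sign flips can give). The arrays did not show this loss equally. The ratio was between -4.60 and -2.88 on the arrays labelled replicates 3 to 10, and -0.20 and -0.25 on the arrays labelled replicates 1 and 2, which goes against the knockout label of those 2 arrays. On these arrays other subunits of the kinase were low. Mnat1 stood at -1.25 on the array labelled replicate 1, against -0.26 to 0.19 on the other 9. Ccnh stood at -1.73 on the array labelled replicate 2, against -0.36 to 0.04 on the other 9, and its other probes read -1.93 and -1.20 there. Across all arrays neither Ccnh (-0.35 ± 0.50, adjusted p = 0.0584) nor Mnat1 (-0.18 ± 0.41, adjusted p = 0.215) passed the test of limma. Ccnh passed without the array labelled replicate 2 (adjusted p = 0.00486), and without the arrays labelled replicates 1 and 2 it stood at -0.19 (adjusted p = 0.00944), while another of its probes read 0.13 to 0.44 on replicates 3 to 10. With trend and robust moderation Ccnh passed on all 10 arrays (adjusted p = 0.0474). Which exons of Cdk7 the allele removes is not given in the sources used here, so the place of the probe relative to the deletion is unknown.

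**Figure D1:**
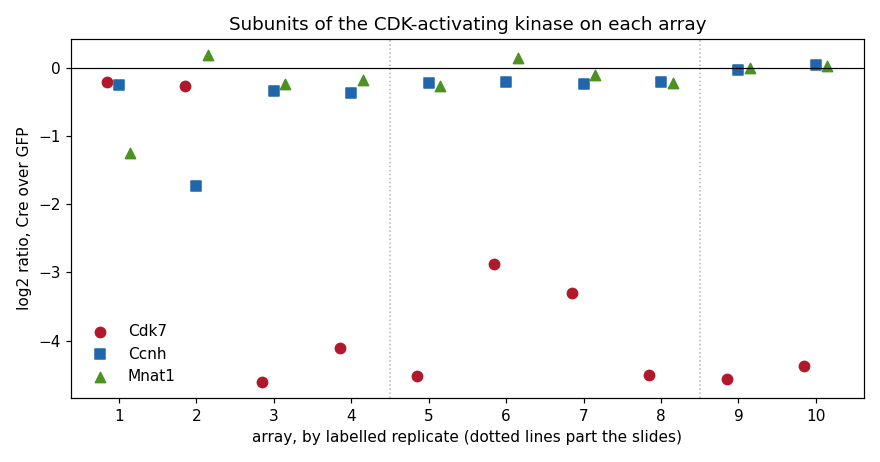
Log2 ratio of Cre over GFP (vertical axis) for Cdk7, Ccnh and Mnat1 on each array, ordered by labelled replicate (horizontal axis), 1 point per gene and array. Cdk7 lies at -0.20 and -0.25 on the arrays labelled replicates 1 and 2 and at or below -2.88 on the other 8, Mnat1 is lowest on the array labelled replicate 1 (-1.25) and Ccnh on the array labelled replicate 2 (-1.73).

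The arrays labelled replicates 1 and 2 also stood apart in their whole profiles. Across genes, which are not independent replicates, their log ratios correlated with each other at r = 0.645. With the arrays labelled replicates 3 to 10, the array labelled replicate 1 correlated at 0.0868 to 0.401 and the array labelled replicate 2 at 0.0559 to 0.331. The dye-swapped array, read as Cre over GFP by its labelled dyes, correlated with the other arrays labelled replicates 3 to 10 at 0.551 to 0.885. Every direction below rests on the labels of all 10 arrays, so each mean and SD pools these 2 arrays with the other 8. Without the arrays labelled replicates 1 and 2 the mean of Cdk7 was -4.11, against -3.33. The median of G2 and mitosis genes was then -1.15, against -0.86, and that of smooth muscle contractile genes 0.49, against 0.52. Leaving out these arrays was a choice made after seeing the data, and other values without them are given where a call differs.

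Of 13881 genes tested, 3582 rose and 3673 fell with Cre at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg). At least 2-fold changes were found for 155 genes that rose and 289 that fell. Without the arrays labelled replicates 1 and 2, 3782 genes rose and 3940 fell, of them 275 and 472 at least 2-fold, and 6821 genes passed in the same direction in both fits. With the slide as a random block, 3196 rose and 3376 fell. Within slide 1, which held the arrays labelled replicates 1 to 4, limma called 0 genes (2747 at an unadjusted p under 0.05), while it called 6266 within slide 2 (4 arrays) and 2904 within slide 3 (2 arrays). The mean Cdk7 log ratio within the slides was -2.29, -3.80 and -4.47, and -3.31 with the slide as a random block. The balance between directions rests on the loess step. With median centring in its place, the median of all genes tested moved from 0.00452 to 0.28, and 85.2% of the genes called rose, against 49.4% with loess. Median centring centres all non-control spots of an array and leaves in any trend of the ratio with brightness. Since Cy5 held the Cre RNA on 9 arrays, such a trend of the dyes cannot be told there from a rise with Cre. Of the genes called with loess, 4058 passed in the same direction with median centring, and changes are given relative to genes of similar brightness. Ratios and medians with median centring stand against that median of all genes. With a dye term 4582 genes passed, and 4124 of the genes called without it were among them in the same direction. Cy5 held the Cre RNA on 9 of 10 arrays, so a dye bias of a gene would mostly count as a change with Cre.

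Among genes with the same sign on all 10 arrays, the largest rises were those of Uts2b, which encodes a urotensin-related peptide (2.82 ± 1.76), Efhd1 (2.08 ± 1.14), the cornified envelope gene Lce1f (2.05 ± 1.23), the keratin gene Krt20 (1.99 ± 1.15), Dntt, the terminal deoxynucleotidyl transferase of lymphocyte precursors (1.99 ± 1.43), and Ica1l (1.98 ± 0.98). They were followed by the skeletal alpha-actin gene Acta1 (1.97 ± 0.81), Pmaip1, which encodes the pro-apoptotic protein Noxa (1.90 ± 0.69), the calponin gene Cnn1 (1.90 ± 0.92), S100a4 (1.89 ± 0.79), the homeobox gene Msx2 (1.79 ± 1.03) and Acsbg1 (1.78 ± 0.91). Lce1f has close relatives in its family, and cross-hybridisation of its probe was not tested. The probes of Uts2b and Msx2 were well above background on 8 arrays in each channel. Those of Lce1f and Krt20 were so on 9 arrays in the Cre channel and 8 in the GFP channel. For these genes a ratio near 0 on an array may come from signals near background. Beside Cdk7, the largest falls were those of Rspo2, a secreted enhancer of Wnt signalling (-2.45 ± 1.31), Gas1 (-2.31 ± 1.27), Itm2a (-2.15 ± 1.12), the interferon-induced gene Rtp4 (-2.15 ± 1.21), Cables1 (-2.14 ± 1.40) and the chromatin remodeller gene Smarca1 (-1.97 ± 0.96). The small leucine-rich proteoglycan genes Aspn (-1.96 ± 0.96), Dcn (-1.90 ± 1.14) and Ogn (-1.90 ± 0.99) also fell, as did Phyhd1 (-1.94 ± 0.68) and the complement gene C1ra (-1.86 ± 0.76). Adjusted p-values of these genes lay between 0.000119 and 0.00200 (limma).

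**Figure D2:**
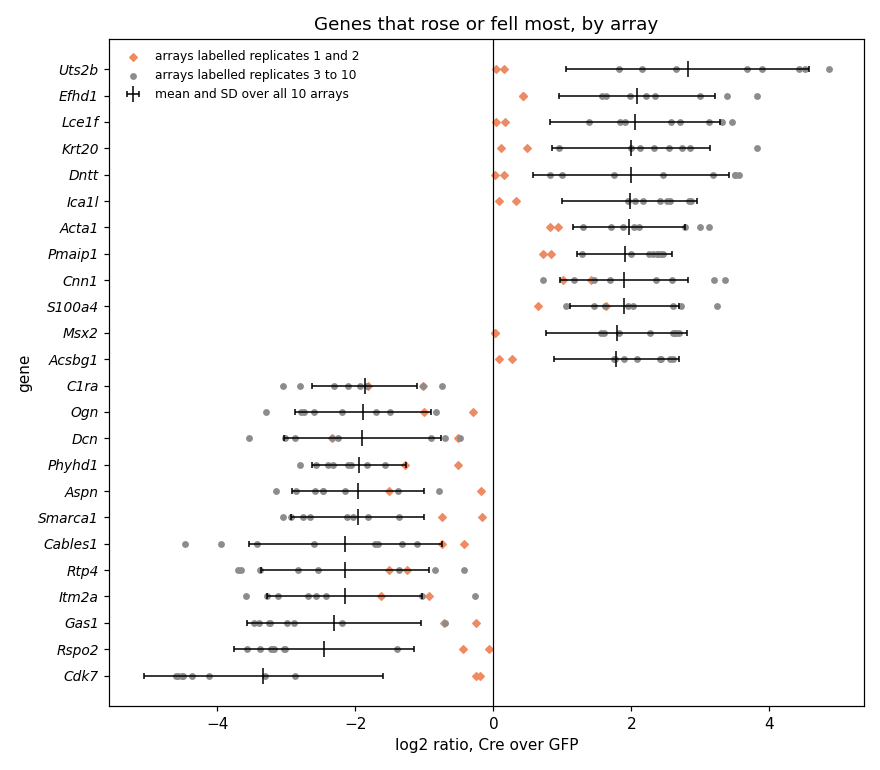
Log2 ratio of Cre over GFP (horizontal axis) of the genes that rose or fell most (vertical axis), with diamonds for the arrays labelled replicates 1 and 2, circles for the other 8 arrays, and bars for the mean and SD over all 10. For Msx2 the arrays labelled replicates 1 and 2 lie at 0.02 and 0.02, while the mean is 1.79. Its probe was well above background on 8 arrays in each channel, so a ratio near 0 may come from signals near background.

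The gene lists below were fixed before the data were examined and were tested with camera at a preset inter-gene correlation. Of 34 lists tested, 14 passed an adjusted p of 0.05, and none of these did with an estimated correlation, as the adjusted p beside each list shows. Statements on single members rest on the limma test of that gene over all genes tested. With a dye term the calls of Ercc2, Polr2i, Slbp, Usp1, Pcna, Fen1, Ccnf, Cdk6, Cdk4, Tnc, Cox7c, Sc5d, Sdf2l1 and Actc1 were lost, and with median centring those of Ercc2, Cdk20, Uhrf1, Rfc5, Prim1, Brip1, Cdkn2d, Gadd45a, Plat and Cdk1, beside the genes whose sign turned. The genes listed for each setting kept the sign of their ratio in it, and with the dye term it stood at 0.79 for Sc5d, 0.31 for Fen1, 0.30 for Slbp and -0.19 for Polr2i, but at -0.0523 for Ercc2 and -0.0720 for Cox7c.

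Genes of mitosis were lower. Of 43 measured genes of G2 and mitosis, 40 fell, 1 rose and 2 did not pass, and the counts adjusted over the list alone were 40 and 1 (median -0.86, camera adjusted p = 1.42e-09; adjusted p = 0.609 with an estimated correlation). They included Cdc25b, a phosphatase that activates mitotic kinase (-1.75 ± 0.56), the kinetochore gene Ndc80 (-1.01 ± 0.59) and Cdk1 (-0.76 ± 0.55). Another probe of Cdk1 read -0.0531, with the same sign on 7 arrays, and other probes of Cdc25b read -0.998 and -0.242. Ccnf rose (0.23 ± 0.23), a call lost without the arrays labelled replicates 1 and 2 (adjusted p = 0.0634, limma). The median of the list was 0.19 and 0.10 on the arrays labelled replicates 1 and 2, and between -1.46 and -0.47 on the other 8.

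Lists of DNA repair and replication genes had medians below 0, and the replication call depended on the setting. Of 21 genes of homologous recombination and the Fanconi pathway, 13 fell and 0 rose, as adjusted over the list alone (median -0.33, camera adjusted p = 0.00151; adjusted p = 0.609 with an estimated correlation), with Fanci (-1.14 ± 0.62) and Brip1 (-0.50 ± 0.31) among them. Of 31 replication genes, 15 fell and 3 rose, or 16 and 3 adjusted over the list alone (median -0.24, camera adjusted p = 0.0168; adjusted p = 0.732 with an estimated correlation). Rfc5 (-0.91 ± 0.49), of the clamp loader, and the primase gene Prim1 (-0.75 ± 0.44) fell, and Pcna, the sliding clamp (0.37 ± 0.31), and Fen1 (0.29 ± 0.28) rose. On the arrays labelled replicates 1 and 2 the medians were 0.16 and 0.11 for repair and 0.23 and 0.02 for replication. The replication call was lost without replicate 7 (camera adjusted p = 0.0562), with a dye term and with the slide as a random block. It was also lost with fry (adjusted p = 0.0626), and with median centring the replication median turned to 0.26.

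Of 28 E2F-regulated genes of the G1/S transition, 12 fell and 4 rose, or 12 and 5 adjusted over the list alone, and the list did not pass (median -0.20, camera adjusted p = 0.101). Uhrf1 (-0.78 ± 0.57) and Usp1 (-0.51 ± 0.34) fell, and the cyclin E gene Ccne1 (0.54 ± 0.23) and Slbp (0.31 ± 0.21), which binds histone mRNA, rose. The median was 0.31 and 0.11 on the arrays labelled replicates 1 and 2, and the list passed without both (adjusted p = 0.00535) and without replicate 1 alone (adjusted p = 0.0201). With median centring the median of the list was 0.25 and Usp1 had a ratio above 0. Of 22 replication-dependent histone genes 14 rose and 5 fell, as adjusted over the list alone (median 0.34, camera adjusted p = 0.0417; adjusted p = 0.609 with an estimated correlation). H4c6 (1.26 ± 0.62) and H4c4 (1.29 ± 0.65) rose and the linker histone genes H1f5 (-0.95 ± 0.40) and H1f4 (-1.08 ± 0.45) fell. On the arrays labelled replicates 1 and 2 the histone median was 0.05 and -0.05. The histone call was lost with processed signals (adjusted p = 0.0770), median centring (0.0520), the authors' value table (0.0546), the stricter filter (0.0568), the mean of probes (0.0739), a dye term (0.108) and the slide as a random block (0.0576). In these settings the histone median lay between 0.34 (stricter filter) and 0.80 (median centring, where the median of all genes was 0.28). Histone genes are near-identical within families, and signal shared between them was not tested.

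Cell-cycle regulators outside these lists moved both ways. Cdkn1a, which encodes the CDK inhibitor p21, rose (0.64 ± 0.24), and the inhibitor genes Cdkn1b (-0.50 ± 0.16), Cdkn2d (-0.62 ± 0.36) and Cdkn2a (-0.19 ± 0.22) fell. Of 7 inhibitor genes 1 rose and 4 fell, as adjusted over the list alone, and the list did not pass (median -0.19, camera adjusted p = 0.265). Of 12 G1 kinase, D cyclin, pocket protein and E2F transcription factor genes 3 rose, among them E2f3 (0.31 ± 0.13) and Cdk6 (0.31 ± 0.25), and 1 fell, Cdk4 (-0.33 ± 0.28), again as adjusted over the list alone (median 0.06, camera adjusted p = 0.342). Cdk2 did not pass (0.01 ± 0.13, adjusted p = 0.808, limma), while it did with median centring (0.17, adjusted p = 0.0372), below the median of all genes there. Another probe of Cdk2 read -0.11 and another probe of Cdk6 -0.0334. With the mean of its probes Cdk6 stood at 0.14 and its call was lost (adjusted p = 0.0907, limma). The Cdkn2a call was lost without replicate 3, 4, 5, 6, 8 or 10 (adjusted p = 0.0558 to 0.0659, limma). With median centring Cdk4 and Cdkn2a had ratios above 0 and the median of the inhibitor list was 0.24.

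Targets of p53 also went both ways, with 12 of 26 that rose and 8 that fell, or 13 and 8 adjusted over the list alone (median 0.18, camera adjusted p = 0.265). Pmaip1 and Mdm2, which encodes the ubiquitin ligase of p53 (0.52 ± 0.19), rose, and Gadd45a (-0.63 ± 0.21) and Sesn1 (-0.98 ± 0.49) fell. Of 30 secreted factors associated with senescence 10 rose and 8 fell, or 11 and 9 adjusted over the list alone (camera adjusted p = 0.55), and the median of 0.07 and the mean of -0.0118 differed in sign. Ereg (1.04 ± 0.40) rose, and the plasminogen activator gene Plat and Igfbp4 (-1.30 ± 0.80) fell.

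Interferon-stimulated genes were lower, and unequally between arrays. Of 35 measured members 30 fell and 0 rose, or 31 and 0 adjusted over the list alone (median -0.81, camera adjusted p = 9.15e-08; adjusted p = 0.609 with an estimated correlation). Ddx58, which encodes the RNA sensor RIG-I (-0.93 ± 0.45), and Ifi44 (-1.45 ± 0.80) were among those that fell. The median was -0.83 and -0.54 on the arrays labelled replicates 1 and 2, -1.64 on replicate 6, -1.33 on replicate 7, -0.04 on replicate 9 and 0.0013 on replicate 10. On replicates 6 and 7 the median of macrophage markers was -0.82 and -0.63, against -0.05 to 0.07 on the other 8 arrays.

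Of 26 collagen and extracellular matrix genes 14 fell and 1 rose, as adjusted over the list alone (median -0.63, camera adjusted p = 0.000630; adjusted p = 0.609 with an estimated correlation). The proteoglycan gene Bgn (-1.02 ± 0.27) and Col6a1 (-1.22 ± 0.61) fell and the tenascin gene Tnc rose (0.64 ± 0.41). Of 14 smooth muscle contractile genes 9 rose and 0 fell, as adjusted over the list alone (median 0.52, camera adjusted p = 0.00458; adjusted p = 0.609 with an estimated correlation), with Cnn1 and Srf, a transcription factor of contractile genes (0.41 ± 0.19), among them. The matrix median was -0.0039 and 0.08 on the arrays labelled replicates 1 and 2 and between -1.64 and -0.50 on the other 8, and the contractile median was 0.37 and 0.42 on those 2 arrays. With median centring the matrix median was 0.0512, with its call kept, and the contractile call was lost (adjusted p = 0.0563), as with a dye term (adjusted p = 0.0540). The matrix call was lost with replicate 4 turned (adjusted p = 0.0700).

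Markers of other tissues were among the genes that rose. Of 8 cardiac muscle markers 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.53, camera adjusted p = 0.0432; adjusted p = 0.609 with an estimated correlation). Nppb, which encodes a natriuretic peptide (1.75 ± 1.06), and the cardiac actin gene Actc1 (0.88 ± 0.53) rose and Tnni3 fell (-0.47 ± 0.41). Of 11 epithelial markers 7 rose and 0 fell, as adjusted over the list alone (median 0.30, camera adjusted p = 0.0432; adjusted p = 0.673 with an estimated correlation), with the keratin genes Krt19 (1.56 ± 1.12) and Krt18 (1.61 ± 1.44) among them. On the arrays labelled replicates 1 and 2 the medians were 0.04 and 0.12 for cardiac and -0.04 and -0.02 for epithelial markers. The median log2 levels in the GFP channel of these arrays were 7.29 and 7.19 for cardiac and 6.88 and 6.86 for epithelial markers. Ratios near 0 there may thus come from signals near background. The cardiac call was lost without the arrays labelled replicates 1 and 2 together (adjusted p = 0.0547) and without replicate 2, 6 or 7 alone (adjusted p = 0.0510, 0.0583 and 0.0549), and the epithelial call without replicate 3, 4, 6 or 7 (adjusted p = 0.0515, 0.0690, 0.0700 and 0.0549). The cardiac call was also lost in 10 other settings (adjusted p = 0.0516 to 0.484) and the epithelial call in 6 (adjusted p = 0.0516 to 0.905), given by setting in the closing section.

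**Figure D3:**
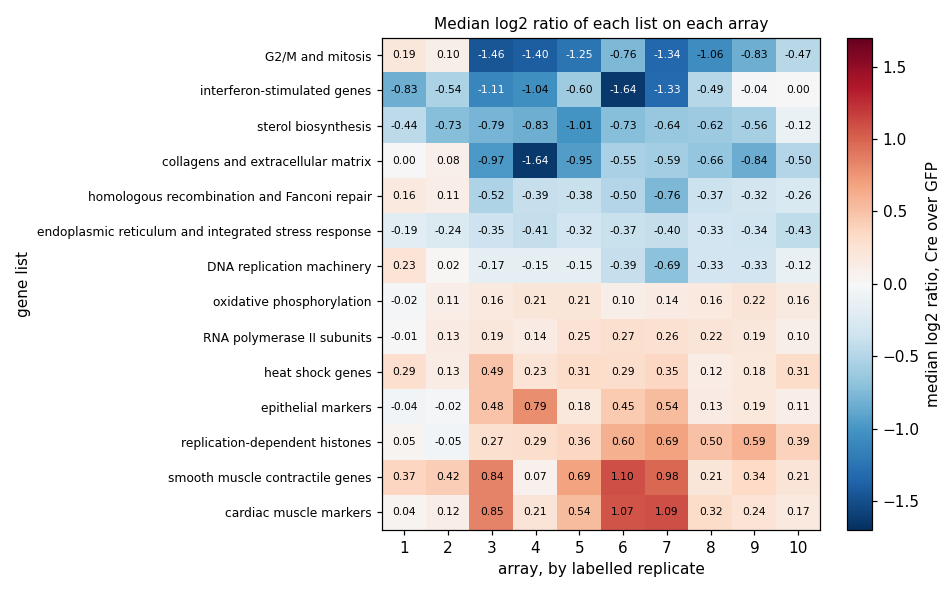
Median log2 ratio of Cre over GFP of each gene list that passed camera (vertical axis) on each array by labelled replicate (horizontal axis), with the median printed in each cell and coloured from blue (lower with Cre) to red (higher with Cre). The G2 and mitosis list lies at 0.19 and 0.10 on the arrays labelled replicates 1 and 2, while the interferon list lies at -0.83 and -0.54 there, and with median centring in place of loess the medians of the replication, matrix and stress response lists lie above 0.

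Of 22 genes of sterol synthesis 20 fell and 1 rose, as adjusted over the list alone (median -0.67, camera adjusted p = 1.34e-08; adjusted p = 0.609 with an estimated correlation). Hmgcs1, which makes HMG-CoA (-1.33 ± 0.34), and Cyp51, a demethylase of sterols (-0.83 ± 0.24), fell and Sc5d rose (0.53 ± 0.67), a call lost without any 1 of replicates 3 to 10 (adjusted p = 0.0503 to 0.0753, limma). Sc5d stood at -0.60 and -0.68 on the arrays labelled replicates 1 and 2 and between 0.36 and 1.12 on the other 8, with a mean of 0.83 without both (adjusted p = 5.46e-05, limma). The sterol median was below 0 on all 10 arrays, with -0.44 and -0.73 on the arrays labelled replicates 1 and 2. Of 20 genes of the endoplasmic reticulum and integrated stress responses 13 fell and 3 rose, as adjusted over the list alone (median -0.29, camera adjusted p = 0.000658; adjusted p = 0.549 with an estimated correlation). The stress response regulators Trib3 (-1.69 ± 0.49) and Atf4 (-0.93 ± 0.26) fell, and the chaperone genes Dnajb9 (0.39 ± 0.36) and Sdf2l1 (0.25 ± 0.23) rose. On the arrays labelled replicates 1 and 2 this median was -0.19 and -0.24, and with median centring it was 0.36 and the call was lost.

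Of 12 heat shock genes 8 rose and 0 fell, as adjusted over the list alone (median 0.27, camera adjusted p = 0.0168; adjusted p = 0.549 with an estimated correlation), with Hspb1 (1.60 ± 0.82) and Hsp90aa1 (0.76 ± 0.38) among them. Of 32 oxidative phosphorylation genes 18 rose and 4 fell, or 19 and 4 adjusted over the list alone (median 0.16, camera adjusted p = 0.00486; adjusted p = 0.609 with an estimated correlation). Ndufa4 (0.47 ± 0.20) and Cox5a (0.64 ± 0.30) rose, and Cox7c (-0.32 ± 0.26) fell but had a ratio above 0 with median centring. On the arrays labelled replicates 1 and 2 the medians were 0.29 and 0.13 for heat shock and -0.02 and 0.11 for oxidative phosphorylation genes, whose call was lost with replicate 4 turned (adjusted p = 0.0550).

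The transcription machinery was looked at next because Cdk7 is part of TFIIH. Of 9 partners of Cdk7 in the kinase and TFIIH, 3 rose and 1 fell, as adjusted over the list alone (median 0.04, camera adjusted p = 0.611), with rises of the helicase gene Ercc3 (0.34 ± 0.16) and of Gtf2h5 (0.24 ± 0.15) and a fall of the helicase gene Ercc2 (-0.16 ± 0.13). Of 13 genes of other transcription kinases and the Mediator kinase module 6 rose and 6 fell, as adjusted over the list alone (camera adjusted p = 0.941), and the median of 0.03 and the mean of -0.03 differed in sign. Cdk8 (0.61 ± 0.41) and Ccnt2 (0.48 ± 0.29) rose and Cdk20 (-0.65 ± 0.28) and Ccnl1 (-0.21 ± 0.15) fell. The list held Cdk20 although it is not an established transcription kinase, so its fall is not read as that of one. Of 8 RNA polymerase II subunit genes 6 rose and 1 fell, as adjusted over the list alone (median 0.22, camera adjusted p = 0.0432; adjusted p = 0.549 with an estimated correlation), with Polr2h (0.30 ± 0.14) and Polr2b (0.33 ± 0.19) higher and Polr2i lower (-0.18 ± 0.15). The polymerase median was -0.01 and 0.13 on the arrays labelled replicates 1 and 2, and its call was lost without both (adjusted p = 0.0570) and without replicate 2, 6 or 7 (adjusted p = 0.0611, 0.0583 and 0.0549). It was also lost with processed signals (adjusted p = 0.0538), the stricter filter (0.0501), the mean of probes (0.0517), replicate 4 turned (0.0650), trend and robust moderation (0.0516) and the slide as a random block (0.0576). With median centring Ccnl1 and Polr2i had ratios above 0. Polr2a and Mki67 were not matched to a probe and were not analysed here.

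Immediate early genes, which respond to growth factors and stress, went both ways, with 9 of 24 that rose and 5 that fell, as adjusted over the list alone (median 0.12, camera adjusted p = 0.408). Fosl1 (1.02 ± 0.53) and Dusp1 (0.64 ± 0.39) rose, and Egr1 (-1.96 ± 0.97) and Jund (-0.37 ± 0.15) fell, the last with a ratio above 0 with median centring.

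The medians of the 14 lists that passed were also taken within slides 1, 2 and 3, and with the slide as a random block. For G2 and mitosis genes they were -0.63, -1.11 and -0.69, and -0.87 with the block. The medians of repair genes were -0.17, -0.45 and -0.29, and -0.32 with the block. For replication genes they were -0.07, -0.39 and -0.20, and -0.23 with the block. The medians of histone genes were 0.22, 0.46 and 0.49, and 0.35 with the block. For interferon-stimulated genes they were -0.92, -1.10 and -0.01, and -0.79 with the block. The medians of matrix genes were -0.53, -0.66 and -0.67, and -0.67 with the block. For contractile genes they were 0.46, 0.71 and 0.30, and 0.47 with the block. The medians of cardiac markers were 0.50, 0.82 and 0.11, and 0.51 with the block. For epithelial markers they were 0.32, 0.42 and 0.11, and 0.31 with the block. The medians of sterol genes were -0.68, -0.73 and -0.35, and -0.66 with the block. For stress response genes they were -0.24, -0.37 and -0.39, and -0.28 with the block. The medians of heat shock genes were 0.26, 0.35 and 0.19, and 0.25 with the block. For oxidative phosphorylation genes they were 0.13, 0.18 and 0.16, and 0.16 with the block. The medians of polymerase genes were 0.15, 0.28 and 0.14, and 0.22 with the block. With the block the calls of the replication, histone, cardiac, epithelial and polymerase lists were lost (adjusted p = 0.0576, 0.0576, 0.0603, 0.0733 and 0.0576).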

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

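The 2 tests that exchanged the conditions at random were planned before their result was seen, and the tests weighed for the 3 patterns below were chosen after it, with the limits for 2 of them made stricter once their values were known, which left both open.

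Exchanging the conditions on random subsets of arrays gave as many changed genes as the real assignment in 1 of 100 patterns, the real one itself, so chance can be excluded for that number. The real one gave 7255 genes with limma and the highest other of those drawn 0, or 8058 and 5875 at an unadjusted p under 0.05. The patterns were drawn from 512 possible ones. None of those drawn exchanged replicate 4 alone, which gave 2285 genes. Excluding chance does not tell Cre from dye, since Cy5 held the Cre RNA on 9 arrays. A dye bias of a gene would thus mostly count as a change with Cre. With a dye term 4582 genes passed, and 4124 of the 7255 were among them in the same direction. For the number of gene lists chance cannot be excluded, since 10 of 100 patterns, the real one included, gave at least the 14 lists called and the highest other gave 17.

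Of 163 results tested, 129 genes and 34 lists, 8 had 1 array far from the others, and chance alone sets apart about 1 in 20. The array labelled replicate 1 stood apart for Mnat1 (-1.25), Gtf2h5 (-0.12 against 0.12 to 0.39), Tnc (1.63 against 0.14 to 0.81) and the oxidative phosphorylation list (median -0.0241 against 0.0973 to 0.22). The array labelled replicate 2 stood apart for Ccnh (-1.73). Replicate 4 did so for Rpl38 (-0.62 against 0.25 to 0.73) and the ribosomal protein list (median -0.79 against -0.14 to 0.55), and replicate 10 for Cyp51 (-0.25 against -1.13 to -0.74).

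Cdk7 was hardly lowered on the arrays labelled replicates 1 and 2. Exchanged dyes are argued against, since the lowest correlation of these arrays with the other 8 was 0.0559 and so not below 0, and a wrong label from outside the series was not tested. On the array labelled replicate 1 the upper quartiles of the interferon and sterol lists lay -0.378 and -0.0400 from the Cdk7 ratio, and on the array labelled replicate 2 -0.0977 and -0.279, where the spread of all genes (interquartile half-width) was 0.116 and 0.128. Interferon genes on the first array and sterol genes on the second thus fell further than a mixture of deleted and undeleted cells allows if their falls came from Cdk7 loss within cells, but incomplete recombination stays open for Cdk7 itself, since falls from the Cre infection could not be told from those of the deletion. Loss of another subunit of the kinase stays open, since the low Mnat1 and Ccnh values on those arrays are what raised it and no independent value tests it.

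The fall of interferon-stimulated genes differed between arrays. The slide is argued against as its whole cause, since the median ranged over 1.15 within slide 2 against a gap of 0.454 between slide 3 and the nearest other array, and so is the extent of Cdk7 loss on the arrays labelled replicates 1 and 2, where even the upper quartiles of the list were at most -0.352. Over replicates 3 to 10 the sign ran against the extent of Cdk7 loss, which needs r above 0: interferon genes fell most on replicates 6 and 7, where Cdk7 was lowered least (-2.88 and -3.31), with r = -0.755 (exact permutation p = 0.0279, adjusted 0.0558 over 2 relations), rho = -0.476 (exact p = 0.243, adjusted 0.243), and without the 2 farthest arrays r = -0.225 (exact p = 0.753), so this relation rests on those arrays and the explanation is neither supported nor excluded there. The interferon level of the GFP cells could also matter and stays open. Over 10 arrays r was -0.621 (permutation p = 0.0594, adjusted 0.0594) and rho -0.539 (permutation p = 0.113, adjusted 0.227). Without the 2 farthest arrays r was -0.914 (exact p = 0.0026). Those were the arrays labelled replicates 1 and 2, on which Cdk7 was hardly lowered. Ratio and level came from different parts of the list but from the same GFP cells. A negative r can thus arise whatever the Cre cells do, so this relation cannot decide the question. Each slide held too few arrays for either relation.

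Ribosomal protein genes were low on replicate 4, the dye-swapped array. Dye bias of bright probes is a candidate explanation. The median dye term of the list was 0.445 (quartiles 0.171 to 0.680), but its sign restates the low value on replicate 4 and is no separate test. With the dye term in the fit the list median was -0.39 (camera adjusted p = 1.27e-08), against -0.04 without it. With 1 swapped array dye bias cannot be told apart from a difference of that preparation. No other biological explanation was tested.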

How the results depend on the processing

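Leaving out the arrays labelled replicates 1 and 2 together was chosen after the result was seen, and the other settings were fixed before the data were examined, except that the median spot signal took the place of the mean, also without background correction. Cdk7 stayed lower and past the threshold in each setting but replicate 4 turned, where it was -2.51 (adjusted p = 0.0602, limma). That setting reverses the labelled dyes of replicate 4, and the values argue against it. With the labelled dyes Cdk7 was -4.12 on that array. The ratios of that array then correlated at 0.551 to 0.885 with the other arrays labelled replicates 3 to 10. Calls lost there thus show the effect of a wrong orientation. The number of changed genes was 4582 with a dye term, 2285 with replicate 4 turned, 14769 with all probes tested and 444 with a 2-fold limit, against 7255, and within 1.5 times of it in the others. Fewer residual degrees of freedom and 1 swapped array limit the dye term, and the signal over background limits dim probes. Every test used the ratio within an array, which pairs the conditions by design, and beyond this no paired analysis was possible because each array gave 1 ratio. Of 128 named genes beside Cdk7, 75 lost their call with replicate 4 turned, 28 with a dye term and 15 with median centring, in addition to those that turned direction, and 0 to 5 in each other setting. Unless said otherwise, the values below are adjusted p of gene lists, and the cause of each change was not tested.

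With an estimated correlation each of the 14 calls was lost, at 0.549 for polymerase, 0.732 for replication, 0.609 for mitosis, histone, repair, interferon, matrix, contractile, oxidative phosphorylation, sterol and cardiac, 0.549 for stress response and heat shock, and 0.673 for epithelial genes. Fry tests whether the genes of a list move, on balance, one way, without comparison with other genes. It called 6 further lists, namely G1 kinases (0.0155), CDK inhibitors (0.00134), p53 targets (0.0109), circadian (0.00662), skeletal muscle (0.00460) and cartilage (0.0109), and not replication (0.0626).

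With median centring 14 named genes turned above 0, namely Ccnl1 (0.20), Polr2i (0.40), Usp1 (0.0404), Cdk4 (0.28), Jund (0.32), Rps15 (0.0519), Rpl14 (0.22), Cox7c (0.28), Acsl1 (0.31), Lamp2 (0.13), Psap (0.43), Cd14 (0.16), Runx2 (0.0659) and Cdkn2a (0.24). Median centring, which leaves in trends of the ratio with brightness, moved the median of all genes tested to 0.28. Of these genes Ccnl1, Usp1, Rps15, Rpl14, Lamp2, Cd14, Runx2, Cdkn2a and, by a hair, Cox7c (0.2801 against 0.2802) lay below it. So did the replication median (0.26), and turned signs thus partly count a shift of all genes. Cdk2 passed there. The replication list turned direction (0.905), the histone (0.0520), contractile (0.0563), stress response (0.790), epithelial (0.905) and cardiac (0.484) calls were lost, and lysosome (0.0122) and macrophage (0.00322) lists passed. With a dye term Rpl38 (-0.0399) and Rpl8 (-0.12) turned below 0, the replication (0.1499), histone (0.108), contractile (0.0540) and cardiac (0.1499) calls were lost, and ribosomal (1.27e-08) and NRF2 (0.0493) lists passed. With the processed signals, the other reading of the plan, the polymerase (0.0538), histone (0.0770) and cardiac (0.0770) calls were lost and the ribosomal list passed (0.01996).

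With the authors' value table the histone (0.0546), epithelial (0.0588) and cardiac (0.0546) calls were lost and the ribosomal list passed (0.00161). With the stricter filter polymerase (0.0501), histone (0.0568) and cardiac (0.107) calls were lost and skeletal muscle passed (0.0486). With the mean of probes polymerase (0.0517), histone (0.0739), epithelial (0.0550) and cardiac (0.0550) calls were lost. With replicate 4 turned polymerase (0.0650), matrix (0.0700), oxidative phosphorylation (0.0550) and epithelial (0.176) calls were lost. Trend and robust moderation ended polymerase, epithelial and cardiac calls (0.0516 each), and the slide block polymerase, replication and histone (0.0576 each), epithelial (0.0733) and cardiac calls (0.0603). The cardiac call was also lost without background correction (0.0540) and without the dim filter (0.0548), and the E2F list passed with array weights (0.0303). An offset of 10 and Aquantile changed no list call.

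Leaving out 1 array at a time gave 0.0201 to 0.271 for E2F, 0.0311 to 0.0611 for polymerase, 0.00293 to 0.0562 for replication, 0.0284 to 0.0700 for epithelial, 0.0351 to 0.0583 for cardiac and 0.0332 to 0.721 for ribosomal genes, which passed without replicate 2 (0.0332). Without the arrays labelled replicates 1 and 2, E2F (0.00535) and ribosomal (0.0136) lists passed and polymerase (0.0570) and cardiac (0.0547) calls were lost.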

Other observations

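The gene lists here were fixed before the data were examined, and the levels by array and the sex check were looked at after the result was seen. None of these lists passed camera, and single genes are given with their limma test. Of genes controlled by NRF2, a regulator of the oxidative stress response, 6 of 14 rose and 2 fell, or 6 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.297). Gclc (0.77 ± 0.43) and Nqo1 (0.82 ± 0.50) rose, and the cystine transporter gene Slc7a11 (-0.64 ± 0.28) and Gstm1 (-0.96 ± 0.51) fell. The NRF2 median was -0.26 and -0.23 on the arrays labelled replicates 1 and 2. Of lysosomal genes 6 of 24 rose and 3 fell, or 5 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.408). Neu1 (0.71 ± 0.65) and Lamp1 (0.34 ± 0.30) rose, and Lamp2 (-0.57 ± 0.29) and Psap (-0.27 ± 0.23) fell, the latter pair with ratios above 0 with median centring. Of circadian genes 6 of 16 rose and 5 fell, or 6 and 6 adjusted over the list alone (median 0.0015, camera adjusted p = 0.698), and the sign of this median changed between settings. Nr1d1 (0.41 ± 0.31) and Bhlhe41 (0.33 ± 0.29) rose, and the clock output genes Dbp (-1.17 ± 0.42) and Tef (-0.64 ± 0.17) fell, while other probes of Tef had the opposite sign. Of cytosolic ribosomal protein genes 2 of 38 rose and 12 fell, or 1 and 12 adjusted over the list alone (median -0.04, camera adjusted p = 0.221). Rps15 (-0.62 ± 0.19) and Rpl14 (-0.33 ± 0.11) fell and Rpl38 (0.43 ± 0.41) and Rpl8 (0.29 ± 0.38) rose, the first pair with ratios above 0 with median centring and the second with ratios below 0 with a dye term. The ribosomal median was 0.0591 without replicate 4 and 0.77 with median centring. Of adipocyte genes 0 of 11 rose and 2 fell, or 0 and 1 adjusted over the list alone (median -0.02, camera adjusted p = 0.617), with falls of Cebpa (-0.44 ± 0.36) and of Acsl1 (-0.22 ± 0.28), whose other probes and whose ratio with median centring had the opposite sign. The Rpl8 call was lost without the arrays labelled replicates 1 and 2 (adjusted p = 0.186, limma) and without any 1 array but replicate 4 or 6 (0.0759 to 0.0980), and the Acsl1 call without any 1 array but replicate 2 or 5 (0.0607 to 0.0957). Without the arrays labelled replicates 1 and 2 the ribosomal list passed camera (adjusted p = 0.0136). With a dye term the calls of Cebpa, Acsl1, Lamp1, Psap, Nr1d1 and Bhlhe41 were lost with the sign of the ratio kept, and with median centring those of Cebpa, Gstm1 and Tef. In the order given, the ratios with the dye term were -0.32, -0.21, 0.33, -0.24, 0.34 and 0.38.

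Markers of cell types are given list by list. Of fibroblast markers 2 of 13 rose and 7 fell, or 2 and 7 adjusted over the list alone (median -0.43, camera adjusted p = 0.211), with rises of S100a4 and Thy1 (0.53 ± 0.49) and falls of Twist1 (-0.69 ± 0.37) and Cd34 (-1.10 ± 0.75). Of macrophage markers 0 of 9 rose and 2 fell, or 0 and 1 adjusted over the list alone (median -0.14, camera adjusted p = 0.221), with falls of Lyz2 (-0.72 ± 0.66) and of Cd14 (-0.14 ± 0.15), the last above 0 with median centring. Of endothelial markers 3 of 9 rose and 1 fell, or 3 and 1 adjusted over the list alone (median 0.03, camera adjusted p = 0.585), with rises of Kdr (0.70 ± 0.49) and Egfl7 (0.38 ± 0.37) and a fall of Robo4 (-0.10 ± 0.08). Of neural markers 4 of 11 rose and 1 fell, or 4 and 3 adjusted over the list alone (median -0.03, camera adjusted p = 0.773) and the mean was 0.20, of the other sign, with rises of Mbp (0.60 ± 0.39) and Nefm (1.11 ± 0.94). Of skeletal muscle markers 4 of 10 rose and 0 fell, or 4 and 0 adjusted over the list alone (median 0.06, camera adjusted p = 0.0981), with rises of Acta1 and Tnnc2 (0.40 ± 0.24). Of erythroid markers 0 of 4 rose and 0 fell, or 0 and 0 adjusted over the list alone (median 0.01, camera adjusted p = 0.719). The median log2 level of erythroid markers in the GFP channel was 6.62 to 6.89, so ratios near 0 may come from signals near background. Endothelial (6.51 to 6.95), skeletal muscle (6.82 to 7.29) and epithelial markers (6.72 to 7.45) were also dim there. Of cartilage and bone markers 1 of 11 rose and 3 fell, or 1 and 3 adjusted over the list alone (median -0.19, camera adjusted p = 0.370), with a rise of Bglap (0.26 ± 0.26) and falls of Runx2 (-0.36 ± 0.23), above 0 with median centring, and Matn3 (-0.35 ± 0.28). Without the arrays labelled replicates 1 and 2 the calls of Cd14 (adjusted p = 0.147) and Robo4 (adjusted p = 0.0944) were lost (limma). Leaving out 1 array also ended the Cd14 call without replicate 1, 2, 3, 5, 6 or 9 (0.0529 to 0.0812) and the Robo4 call without replicate 1, 2, 4, 5, 8 or 10 (0.0518 to 0.0647). With a dye term the calls of Thy1, Cd34, Lyz2, Cd14, Robo4, Mbp, Tnnc2 and Matn3 were lost with the sign of the ratio kept, and with median centring those of Twist1 and Lyz2. In the order given, the ratios with the dye term were 0.28, -0.92, -0.91, -0.07, -0.14, 0.56, 0.34 and -0.40.

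In the GFP channel the median log2 level of cartilage and bone markers was 10.9 and 10.8 on the arrays labelled replicates 1 and 2, and 6.96 to 8.25 on the other 8. That of macrophage markers was 8.14 and 7.97 on replicates 6 and 7, and 6.49 to 7.24 on the other 8. Of 5 sex-linked genes listed 1 passed the filter, Xist (0.04 ± 0.29, adjusted p = 0.744, limma), and 3 were looked at by array. The mean log2 intensity of Eif2s3y was 12.1 and 11.9 on replicates 7 and 8 and at most 7.08 on the other 8, and that of Xist was 5.95 and 5.94 on replicates 7 and 8 and at least 8.15 on the others. Across genes, which are not independent replicates, the log ratios of replicates 6 and 7 correlated at r = 0.940, the highest of all pairs, although these 2 arrays differed in both genes.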
